A study of Danio rerio with 3 samples.

How the data were processed

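RNA of psen1 mutant and wild-type zebrafish brain was co-hybridised on 2-colour arrays. Per the labels' protocols, total RNA of pooled brains was amplified, labelled with Cy3 or Cy5 and hybridised to the Agilent 22K array. Per the labels, each of the 3 biological replicates was scanned as a dye-swapped pair of 2 arrays. The deposited values are 1 log ratio per probe and replicate, read here as log2 ratios of mutant over wild type. The direction comes from the sample titles. The log base, the background correction, the normalization and the way the dye-swapped pair was combined are not given in the sources used here. The medians of the 3 columns lay near 0, and the log ratios were analysed as deposited.

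Probe genes came from the platform annotation in the table given with the series. Of the 11929 listed probes, 11819 matched a gene ID in a RefSeq gene table of assembly GRCz12tu, which was used for current names and for neighbouring genes only. Of the probes with a value in all replicates, 11929 had 1 gene, 0 had several and 9565 had none listed, and unlisted probes entered the probe-level test only. All probes of a gene were averaged per replicate. Of 2458 genes with more than 1 probe, 869 had probes whose mean ratios differed in sign, none of them among the genes named by the rule below.

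Each replicate counted as 1 sample, n = 3. The mean log ratio was tested against 0 with limma (version 3.58.1, R 4.3.3; lmFit with an intercept only and eBayes, two-sided), at probe level and at gene level. The p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Errors given after ± are the SD of the 3 replicates. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over 44 lists, and members were also counted after adjustment over the list alone. Tables were read with data.table (version 1.17.8) and plots drawn with matplotlib 3.10.9 in Python 3.11.15.

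The genes named were chosen by a rule fixed before the data were examined. It took psen1 and psen2, the 12 highest and 12 lowest genes among those that passed, and members of each list. Where fewer than 12 passed in a direction, places were filled by the smallest unadjusted p with the same sign in all 3 replicates, and clone names were skipped. Because 0 genes passed, all 24 places were filled that way. Up to 4 members per list were named where they passed over the list alone, otherwise the 2 with the largest moderated statistic. Genes outside the rule are said to have been chosen after their values were seen.

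The steps were tested on simulated data. For the comparison at gene level with 8858 genes, 50 genes were shifted at each size. A shift of 0.5 was called for 18% of them, 1 for 66%, 2 for 98% and 4 for 100%, with 3 false calls. For the gene lists, 5 of 20 simulated lists were shifted by 0.3. The preset correlation found 5 and the estimated correlation 3, with 0 false lists. Genes were drawn independently there, so false calls in lists whose members move together were not tested.

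Alternatives were median centring, scale and quantile normalization, leaving out each replicate, a plain one-sample test, robust eBayes, treat against a 1.2-fold change, array weights, a looser threshold of 0.10 and rows with values in at least 2 replicates. Further ones were the probe with the smallest SD per gene, genes with 1 probe, an estimated correlation, camera on ranks and fry. Scale normalization was planned with normalizeBetweenArrays, which takes logs of the column medians of a plain matrix and gave no values here, so normalizeMedianAbsValues was applied after median centring. Members called over each list without replicate 3, and lists tested after dividing each replicate by its SD, were added after the data were seen. No rows had 3 identical or zero ratios, so the filter on them removed nothing. The psen1 transcript was not analysed, since no probe was listed for it.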

Results

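Whole-brain RNA of zebrafish carrying the hu2547 allele of psen1 was compared with wild-type RNA at 17 months of age on Agilent 22K arrays of 60-mer probes. The gene psen1 encodes presenilin 1, the catalytic subunit of gamma-secretase, which cleaves APP, Notch and other membrane proteins. Each RNA came from a pool of 3 to 4 brains. The 3 biological replicates each paired 1 mutant pool with 1 wild-type pool, hybridised in both dye orientations and deposited as 1 column of log ratios. A positive ratio stands for more transcript in the mutant, as the sample titles name the ratio. The log base is not given in the sources used here and was taken as 2, and folds rest on that reading. Of 21495 probes, 21494 had a value in all 3 replicates, and 11929 of these carried 1 listed gene, which gave 8858 genes. Signal intensities were not used here. The number of arrays limits the precision.

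The targeted gene could not be read out. No probe was listed for psen1, so the genotype labels were not checked by the transcript itself. Its paralogue psen2 had a mean log ratio of -0.09 ± 0.16 (SD, n = 3), with an adjusted p of 0.824.

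The replicates did not move alike. Replicates 1 and 2 were correlated across probes (Pearson r 0.487, Spearman rho 0.268). Replicate 3 was nearly uncorrelated with replicate 1 (r 0.0418, rho -0.0673) and with replicate 2 (r 0.107, rho 0.0441). Probes are not independent replicates, and these values describe the 3 columns only. The SD of the log ratios was 0.225, 0.208 and 0.371 in replicates 1, 2 and 3, and the medians were 0.0044, 0.0061 and 0.0028.

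**Figure D1:**
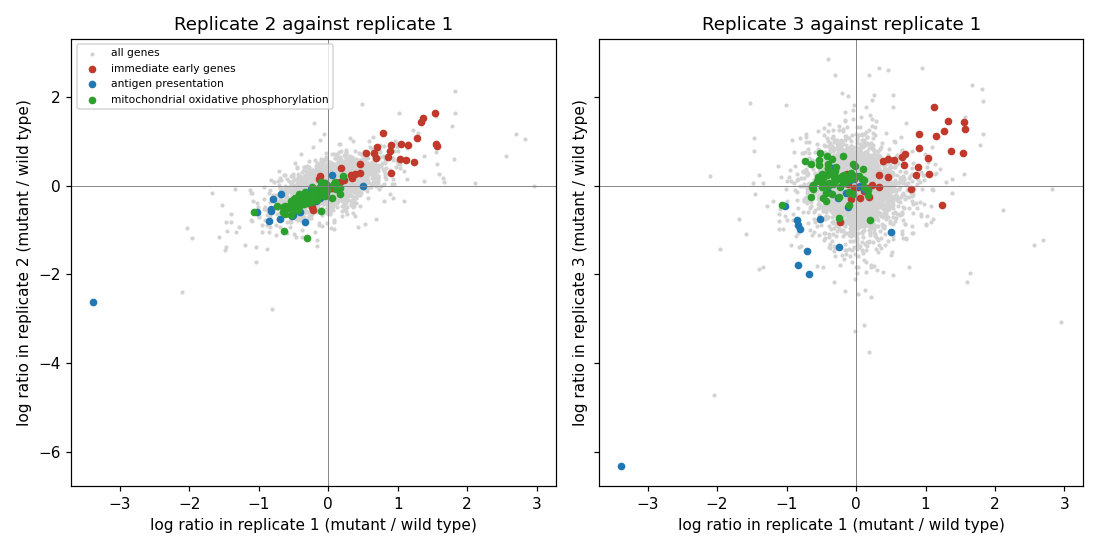
Log ratios of psen1 mutant over wild type per gene in replicate 2 (left) and replicate 3 (right), each against replicate 1, with 1 grey point per gene and 3 fixed gene lists in colour. Immediate early genes (red) lie mostly above 0 on both axes in both panels, whereas oxidative phosphorylation genes (green) have a median of -0.31 in replicate 1, -0.29 in replicate 2 and 0.16 in replicate 3.

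The 12 genes with the smallest p in each direction, none of which passed over all genes, had the following ratios. The zinc-finger factor egr2b had a log ratio of 1.41 ± 0.07 (SD, n = 3), a 2.65-fold ratio. The AP-1 subunits junbb, fosab and junba stood at 1.19 ± 0.10, 0.99 ± 0.16 and 0.67 ± 0.05. The value of fosab averages 2 unlike probes, of which 1 had a mean of 1.55 (adjusted p 0.074 in limma over all probes). The MAP kinase phosphatases dusp2 and dusp5 stood at 1.06 ± 0.13 and 0.76 ± 0.09, and the signalling inhibitor spry4 at 0.86 ± 0.14. The others with positive ratios were fah, the last enzyme of tyrosine breakdown (2.83-fold, with a log-ratio SD of 0.09), the ribosome assembly factor rpf2 (1.54 ± 0.35), sox4b (0.75 ± 0.06), the clock repressor nr1d2b (0.71 ± 0.11) and arglu1b (0.68 ± 0.11). At the low end were brain aromatase cyp19a1b (-1.53 ± 0.40), the vasopressin-type hormone gene avp (-1.28 ± 0.26), the interferon regulatory factor irf1b (-0.96 ± 0.16) and the galectin lgals9l1 (-0.89 ± 0.04). The peroxiredoxin prdx6 (-0.82 ± 0.08), the proteasome activator subunit psme2 (-0.81 ± 0.03), psmb10 (-0.77 ± 0.17), cd74a (-0.66 ± 0.12) and the macrophage gene mpeg1.1 (-0.59 ± 0.05) also had negative ratios. The remaining genes with negative ratios were zc2hc1a (-0.87 ± 0.19), kdelr2a (-0.81 ± 0.17) and arpc4 (-0.48 ± 0.03).

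None of these genes passed the test over all genes. With limma, 0 of 8858 genes and 0 of 21494 probes reached an adjusted p under 0.05. At an unadjusted p under 0.05 there were 705 genes, 365 higher and 340 lower, against 443 given by chance, and 1398 probes against 1075. The lowest adjusted p was 0.0508, shared by zgc:122979 (1.95 ± 0.15), egr2b and fah, the 3 genes under 0.10. The first of these carries a clone name and was added after its value was seen. The 3 ratios had the same sign for 30.6% of genes, against 25% for 3 independent columns. The first 2 replicates were correlated with each other (Pearson r 0.487 across probes), which by itself can raise that share above 25%. The excess therefore does not show that replicate 3 moved with the other replicates. Without replicate 3, 510 genes and 638 probes were called, 272 genes higher and 238 lower, and with array weights 33 genes and 4 probes. Of the 510 genes, 283 (55.5%) had the same sign in replicate 3.

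**Figure D2:**
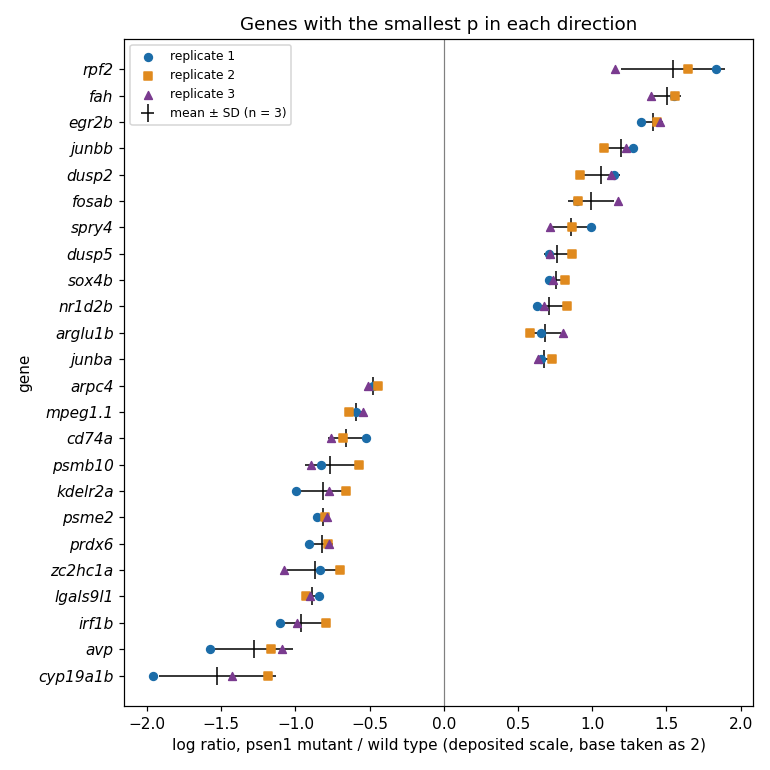
Log ratios of psen1 mutant over wild type (horizontal axis, base taken as 2) for the 12 genes with the smallest p in each direction, with 1 symbol per replicate, the mean as a vertical bar and the SD as a horizontal line. All 3 replicates lie on the same side of 0 for each gene, from cyp19a1b at a mean of -1.53 to rpf2 at 1.54, and genes were picked for that property.

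Of 44 gene lists fixed before the data were examined, 2 were shifted higher and 8 lower against all other genes (camera with a preset correlation of 0.01, adjusted p under 0.05). With an estimated correlation 0 of the 44 were called (lowest adjusted p 0.438). That setting takes p from the 2 residual degrees of freedom of the fit, so its p-values run higher than at the preset correlation. The immediate early genes, which neurons and other cells switch on within minutes of stimulation, were the list with the lowest p. Of 38 measured members, 22 were higher and 1 lower adjusted over the list alone, and 0 passed over all genes. The list's median log ratio was 0.51, with 0.60, 0.50 and 0.26 in replicates 1, 2 and 3. Besides egr2b, the largest were ier2a (1.31 ± 0.33, SD, n = 3), the nuclear receptor nr4a1 (2.46-fold, with a log-ratio SD of 0.497) and the stress sensor gadd45ba (1.25 ± 0.34). The lower member, klf2b (-0.51 ± 0.29), was named after its value was seen. Without replicate 3, 26 members were higher and 2 lower over the list alone. The adjusted p of the list was 8.2e-17, and 0.438 with an estimated correlation, so the call was lost there.

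The circadian clock list was also shifted higher at the preset correlation (adjusted p 1.0e-04), but not with an estimated correlation (adjusted p 0.438). Its median was 0.13, with 0.09, 0.13 and 0.11 in the 3 replicates, and 13 of 32 measured members lay above 0 in all of them. Over the list alone 1 member, nr1d2b, was higher, and without replicate 3 there were 12 higher and 2 lower. A different question, whether a list's members move one way on balance without comparing them with other genes, was asked with fry. It called this list alone (adjusted p 0.0314). As fixed, the circadian list has per1a and per1b in common with the immediate early list.

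The list of genes that process and present antigen was shifted lower at the preset correlation (adjusted p 2.2e-10), but not with an estimated correlation (adjusted p 0.438). Of 22 measured members, 10 were lower and 0 higher adjusted over the list alone, and 0 passed over all genes. The class I gene mhc1uba had log ratios of -3.38, -2.63 and -6.31 in the 3 replicates, a mean of -4.11 ± 1.95 (SD, n = 3). Among the 10 members that passed over the list alone, the next lowest were the immunoproteasome subunits psmb13a (-1.05 ± 0.66) and psmb12 (-0.97 ± 0.44) and the activator subunit psme2. The list's median was -0.37, with -0.37, -0.33 and -0.47 in replicates 1, 2 and 3. Without replicate 3, 14 members were lower over the list alone.

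The interferon response list was lower too (22 measured, median -0.14, adjusted p 4.5e-05, and 0.749 with an estimated correlation). Its median was -0.15, -0.02 and -0.28 in replicates 1, 2 and 3. Besides psmb10, its members b2m, psmb8a and psmb9a, named after their values were seen, are also in the antigen list. Of these, psmb8a (mean -0.56) and psmb9a (-0.95) lie in the block around mhc1uba treated below. The 3 interferon members lower over the list alone were irf1b, psmb10 and the guanylate-binding protein gene gbp1 (-0.61 ± 0.27). Without replicate 3 there were 6 lower and 1 higher. The microglia and macrophage list had a median of -0.10 over 35 members (adjusted p 0.00068, and 0.44 with an estimated correlation). In all 3 replicates 15 members were lower and 4 higher, and 16 were mixed. Over that list alone 5 members were lower, among them lgals9l1, mpeg1.1, cd74a and rac2 (-0.45 ± 0.10), and cd74a again belongs to the antigen list. The macrophage gene mfap4.1, named after its values were seen, went the other way (mean 1.16 in replicates 1 and 2, and 0.25 in replicate 3). Without replicate 3, 11 were lower and 3 higher. Other leukocyte genes did not pass (adjusted p 0.632), with cxcr4a at 0.31 ± 0.11 and ikzf1 at -0.37 ± 0.20.

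**Figure D3:**
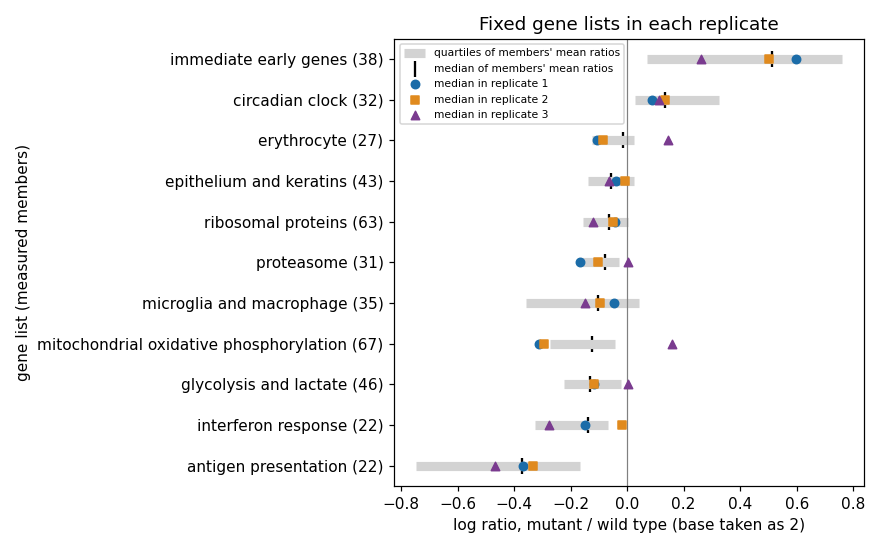
Median log ratio of psen1 mutant over wild type (horizontal axis, base taken as 2) in each replicate for the 10 shifted gene lists and the erythrocyte list, with the number of measured members in brackets, grey bars for the quartiles of the members' mean ratios and a black tick for their median. The medians of immediate early, circadian, epithelium, ribosomal, microglia, interferon and antigen genes keep their side of 0 in all 3 replicates. Those of oxidative phosphorylation (0.16), erythrocyte (0.14), glycolysis (0.003) and proteasome genes (0.003) lie above 0 in replicate 3 only.

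Oxidative phosphorylation genes had medians of opposite sign by replicate. The mitochondrial oxidative phosphorylation list was lower (67 measured, median -0.12, adjusted p 7.1e-06, and 0.749 with an estimated correlation), but its median was -0.31, -0.29 and 0.16 in replicates 1, 2 and 3. No member passed over the list alone, and without replicate 3 there were 43 lower and 1 higher. The cytochrome oxidase subunits cox6a1 (-0.37 ± 0.06) and cox6b2 (-0.43 ± 0.15) had the largest statistics. Erythrocyte genes, which mark blood in the tissue, had medians of -0.11, -0.09 and 0.14 in replicates 1, 2 and 3, and 0 of 27 passed over the list alone. Glycolysis and lactate genes had a median of -0.13, with -0.12, -0.12 and 0.003 in the 3 replicates (adjusted p 0.00068, and 0.438 with an estimated correlation), and 0 members passed over the list alone. Within it gapdh stood at 0.42 ± 0.23 and eno1b at -0.36 ± 0.20. Without replicate 3 there were 18 lower and 3 higher.

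Smaller shifts were seen in 3 further lists. Proteasome genes had a median of -0.08 (adjusted p 0.0017, and 0.749 with an estimated correlation), with psmc1a at -0.40 ± 0.11 and psma5 at -0.57 ± 0.24. Ribosomal protein genes had a median of -0.06 (adjusted p 0.0034, and 0.438 with an estimated correlation), with rps20 at -0.31 ± 0.06 and rps8b at -0.22 ± 0.07. Epithelium and keratin genes had a median of -0.06 (adjusted p 0.0268, and 0.517 with an estimated correlation). In the last list anxa3b (-0.63 ± 0.17) and jupa (-0.50 ± 0.06) were lower over the list alone, and in the proteasome and ribosomal lists 0 members passed. Without replicate 3, 11 proteasome members were lower and 1 higher, 1 ribosomal member was lower, and 6 epithelium members were lower. Leaving out a replicate ended the proteasome call without replicate 1 (adjusted p 0.107) or 2 (0.0594), and the oxidative phosphorylation call without replicate 2 (0.0638). It ended the ribosomal call without replicate 3 (0.062) and the epithelium call without replicate 1 (0.0738) or 3 (0.0846).

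The pathways closest to presenilin did not pass the test. The gamma-secretase and APP processing list had an adjusted p of 0.602 over 15 measured members. Its beta-secretase gene bace1, whose product makes the first cut in APP, stood at -1.25 ± 0.42 and was the 1 member lower over the list alone. The Notch list had an adjusted p of 0.535 over 31 members, with the Notch target genes her6 at -0.39 ± 0.23 and hey1 at -0.17 ± 0.19. The Wnt and beta-catenin list had an adjusted p of 0.93, with sp5a at 0.35 ± 0.07 and ctnnb2 at -0.28 ± 0.13.

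Lists of neuronal function did not pass with all 3 replicates. Without replicate 1, neuronal markers (adjusted p 0.0084) and synaptic vesicle genes (0.039) were called higher. With all replicates, adjusted p was 0.315 for monoamine and histamine genes, with th2 at 0.19 ± 0.03 and hrh3 at 0.23 ± 0.12. It was 0.189 for hypothalamic neuropeptides, where avp was lower over the list alone. Glutamatergic genes (0.466) included gria4b at 0.18 ± 0.06 and gria3b at -0.12 ± 0.08. GABAergic and glycinergic genes (0.93) included slc6a9 at -0.23 ± 0.07 and dlx5a at -0.21 ± 0.11. In the cholinergic list (0.535) the receptor subunit gene chrna5 (0.37 ± 0.08) was higher over the list alone. Synaptic vesicle genes (0.466) included syt4 at 0.39 ± 0.17 and vamp8 at -0.30 ± 0.18. Neuronal markers (0.603) included stmn4 at -0.89 ± 0.41 and inab at 0.27 ± 0.04, and calcium handling genes (0.625) pvalb8 at -0.44 ± 0.19 and hpca at 0.29 ± 0.14.

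Lists of neurogenesis, radial glia, oligodendrocyte, vascular, meningeal and choroid plexus genes, and of steroid and thyroid hormone genes, did not pass with all 3 replicates. The radial glia list was called lower without replicate 3 (adjusted p 0.00016) and the vascular list lower without replicate 1 (0.0174). In the neurogenesis and proliferation list (adjusted p 0.466) mcm7 (0.85 ± 0.26), sox4b and sox11a (0.57 ± 0.06) were higher over the list alone. In the radial glia list (0.132) cyp19a1b was lower over the list alone, as it was in the steroid and thyroid hormone list (0.298). Oligodendrocyte genes (0.624) included pou3f1 at 0.23 ± 0.04 and scdb at -0.21 ± 0.24. Vascular genes (0.172) included cldn5b at -0.48 ± 0.12 and tal1 at 0.43 ± 0.23. Matrix and meningeal genes (0.0979) included mmp14a at -0.36 ± 0.23 and ptgdsb.1 at 0.36 ± 0.24. Choroid plexus and cilia genes (0.298) included tekt1 at -0.25 ± 0.08 and cfap298 at 0.27 ± 0.11.

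Stress and lipid lists did not pass with all 3 replicates as deposited. Without replicate 3, heat shock (adjusted p 0.00019), unfolded protein response (0.0104) and p53 genes (0.0281) were called higher and oxidative stress genes lower (9.8e-07). Without replicate 1, cholesterol genes were called higher (0.0081). Heat shock and oxidative stress genes also passed after scale (0.0179 and 0.015) and quantile normalization (0.0175 and 0.0089). The cytosolic heat shock list had an adjusted p of 0.0561, with hsp90aa1.2 at 0.83 ± 0.23 and fkbp4 at 0.37 ± 0.17. The oxidative stress list had the same adjusted p, and prdx6 was lower over the list alone. The unfolded protein response list (0.315) held ero1a at -0.83 ± 0.24 and hsp90b1 at 0.48 ± 0.22. The p53 and apoptosis list (0.132) held gadd45ab at 0.62 ± 0.17 and cdkn1ba at 0.38 ± 0.08. In the cholesterol list (0.117) lpin1a (0.75 ± 0.23) and aclya (0.42 ± 0.11) were higher over the list alone, and in the lipid transport list (0.466) pltp was lower (-0.61 ± 0.15). Lysosome and autophagy genes (0.666) included ctsh at -0.38 ± 0.04 and becn1 at -0.97 ± 0.46, and vacuolar ATPase genes (0.81) atp6v1d at 0.36 ± 0.32 and atp6v0a1a at 0.20 ± 0.22. The vacuolar ATPase list was called lower without replicate 3 (adjusted p 0.0465).

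Lists of cytokine, complement, erythrocyte, muscle, pituitary, retina and liver genes did not pass with all 3 replicates. Without replicate 3 the erythrocyte list was called lower (adjusted p 2.9e-05), with 9 members lower over the list alone. Cytokine and NF-kB genes (adjusted p 0.603) included socs3a at 1.34 ± 0.44 and nfkbiab at 0.72 ± 0.27, and complement genes (0.696) cfd at 0.30 ± 0.04 and cp at -0.68 ± 0.33. The erythrocyte list (0.315) included nt5c2l1 at -1.43 ± 1.43 and tspo at 0.30 ± 0.27. Muscle genes (0.666) included tpm2 at 0.35 ± 0.07 and mylpfb at -0.33 ± 0.06. Pituitary genes (0.466) included pomca at -0.52 ± 0.45 and prl at -0.08 ± 0.03. Retina, lens and pineal genes (0.404) included opn1lw1 at -0.70 ± 0.32 and pde6ha at -0.96 ± 0.54, and liver and yolk genes (0.315) cp and ttr at -0.11 ± 0.09.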

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

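Alternatives fixed before the data were examined left 0 genes and 0 probes called with median centring, scale normalization, the plain one-sample test, robust eBayes, treat and values in at least 2 replicates. Genes with 1 probe also gave 0. Probes called were 1 with quantile normalization, 3 at an adjusted p under 0.10 and 4 with array weights. Genes called were 3 at an adjusted p under 0.10, 3 with the smallest-SD probe and 33 with array weights, which gave replicate 3 a weight of 0.306 against 1.21 and 2.71. Leaving out 1 replicate gave 0 to 638 probes and 0 to 510 genes, the highest values without replicate 3. The self-test at n = 3 called 18% of genes shifted by 0.5 and 66% of those shifted by 1, with larger shifts seeded beside them. It therefore cannot tell whether sample size accounts for the 0. None of the 99 named genes changed sign under these settings. Most had the same sign in all 3 replicates, so leaving out or reweighting a replicate could not change their sign. Without replicate 3, 68 of the 99 were called, but replicates 1 and 2 took part in choosing most of them, which favours a high share. Over named probes or after quantile normalization r was 0.579 and 0.492 for replicates 1 and 2, 0.0412 and 0.0364 for 1 and 3, and 0.128 and 0.111 for 2 and 3. The psen1 transcript had no value under any setting.

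Of the 10 shifted lists, 10 were called with median centring, and 12 lists were called with scale or quantile normalization and after dividing by the SD, the last chosen after the data were seen. Leaving out 1 replicate gave 8 to 15 lists. Adjusted p then ranged from 7.7e-06 to 0.107 for the proteasome, 0.0243 to 0.0846 for epithelium, 5.1e-22 to 0.0638 for oxidative phosphorylation and 0.0078 to 0.062 for ribosomal proteins. The vacuolar ATPase list, not called with all replicates, turned lower without replicate 3, with an adjusted p of 0.0465 to 0.487 when 1 replicate was left out. Camera on ranks called 9 lists and lost epithelium (0.0639). An estimated correlation called 0 lists. Adjusted p was 0.438 for immediate early, circadian, antigen, glycolysis and ribosomal genes, 0.44 for microglia, 0.517 for epithelium and 0.749 for interferon, oxidative phosphorylation and proteasome genes. With an estimated correlation camera takes p from the 2 residual degrees of freedom of the fit. At the preset correlation it takes p from about as many degrees of freedom as genes. The estimate lay below the preset 0.01 for antigen (-0.016), circadian (-0.00695), glycolysis (-0.000832), ribosomal (-0.0054), epithelium (-0.0184) and microglia genes (0.00996). In those 6 lists a higher correlation between members therefore does not account for the lost call, which leaves the fewer degrees of freedom. For antigen genes the unadjusted camera p went from 1.0e-11 to 0.0174. The estimate was 0.0838 for immediate early, 0.0979 for proteasome, 0.278 for interferon and 0.531 for oxidative phosphorylation genes. With fry 1 list, the circadian clock, was called. Adjusted p there was 0.0891 for immediate early and antigen genes, 0.141 for microglia and glycolysis, 0.166 for epithelium, 0.314 for ribosomal, 0.488 for interferon, 0.568 for proteasome and 0.59 for oxidative phosphorylation genes. For the lists with an estimate above the preset, and for fry, the cause of the lost calls was not tested. Each deposited column is a ratio within 1 pair of pools, so the test against 0 is itself the paired test, and no unpaired fit was run.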

Other observations

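All tests of explanations below were chosen after the results were seen, and their bounds for blood, exchange, antigen genes outside the block, microglia, stress hormone and time of day were revised after the first values were known. The counts over sign assignments were planned before they were seen.

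The genes fkbp5, cebpd and trib3 were high in replicates 1 and 2 and below 0 in replicate 3, and were picked after their values were seen. The log ratios of fkbp5 were 2.70, 1.16 and -1.23 in replicates 1, 2 and 3. Those of cebpd were 2.83, 1.04 and -0.07, and those of trib3 2.56, 0.67 and -1.33. None of them passed over all genes (adjusted p 0.822, 0.712 and 0.861).

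Replicate 3 followed replicates 1 and 2 weakly. Random noise added to a shared effect would leave the slope on replicate 1 unchanged, but the slope of replicate 3 was 0.0766 times that of replicate 2 (95% bootstrap interval over genes -0.126 to 0.286), which argues against noise as the whole cause if replicates 1 and 2 share a genotype effect. An exchange of genotypes in replicate 3 stays open: 283 of 510 genes called without it (55.5%, exact interval 51.1% to 59.9%, genes not independent) had the same sign in it, while turning its sign gave 11 shifted lists against 10. Of the 15 lists called without replicate 3, members with the list's direction in replicates 1 and 2 mostly kept it in replicate 3 in 6 lists (23 of 29 immediate early, 14 of 18 antigen genes), mostly turned in 7 (14 of 56 oxidative phosphorylation genes kept it) and were split evenly in 2. A difference in blood content could not be decided, since leaving out the 27 erythrocyte genes moved r between replicates 1 and 3 over genes only from 0.0253 to 0.0295.

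The lower antigen presentation genes may include an effect of strain sequence. Of the 22 members, 7 lie together around mhc1uba in the gene table (median -0.95), and there lower transcript and a poorer match of a different MHC haplotype to the probes cannot be told apart from ratios alone. The 15 members outside that block had a median of -0.29 (quartiles -0.52 to -0.08), with 8 lower and 0 higher in all 3 replicates. They were shifted lower by camera (unadjusted p 1.7e-07 at the preset correlation and 0.0306 with an estimated one). That argues against such a haplotype as the whole cause there, although they are part of a list already called lower in the same data. With an estimated correlation the whole list had an unadjusted camera p of 0.0174 and lost its call (adjusted p 0.438). Fewer microglia stay open as well: microglia and macrophage genes outside the antigen and interferon lists had a median of -0.0673 over 30 members (camera p 0.0015). Of these members, 13 were lower and 4 higher in all 3 replicates. Their difference from the 15 antigen members had a p of 0.0728 in a permutation over genes, which are not independent. A genotype effect on antigen presentation is a hypothesis that these values leave open.

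The higher immediate early genes could reflect how or when the brains were taken, or the genotype, and the tests here decide none of these. A stress hormone response is undecided, because the 6 glucocorticoid-responsive genes went both ways and their lowest median over the replicates was -0.0571. Among them are fkbp5 and cebpd, which were high in replicates 1 and 2 and below 0 in replicate 3, as given above. The opposite order was seen for mt2 (-0.16, -1.22 and 1.65 in replicates 1, 2 and 3), named after its values were seen. A different time of day is undecided: the circadian list was higher (adjusted p 1.0e-04), but not with an estimated correlation (adjusted p 0.438), and bmal1a, expected to move the other way, stood at -0.19 with an unadjusted p of 0.178 in limma. Shared members per1a and per1b also keep the circadian shift from being wholly separate from that of the immediate early list. A longer or rougher dissection of the mutant pools cannot be told apart from genotype, since it too would raise the immediate early list in every replicate (lowest median 0.26).

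Sequence carried along with the psen1 allele was tested on the 50 measured genes nearest to psen1 on its chromosome. Of these 6 (12%) had an unadjusted p under 0.05, against 7.94% of other genes (one-sided Fisher's exact test, p = 0.204), so an excess was not shown and the explanation stays open. The 3 with the smallest p, named after their values were seen, were eipr1 (-0.88 ± 0.25, SD over the replicates), egr2a (1.23 ± 0.39), which is also in the immediate early list, and atxn3 (0.62 ± 0.20). None passed in limma over all genes (adjusted p 0.277, 0.277 and 0.311). Of the 3 probes of eipr1, 1 had ratios of -1.40, -1.24 and -1.51 in replicates 1, 2 and 3 (adjusted p 0.138 over all probes), and the other means were -0.86 and -0.40.

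The 3 ratios allow 4 sign assignments, too few for a share under 0.05. For gene lists the real assignment called 10, and turning replicate 3 called 11, so 2 of the 4 gave as many. For genes and for probes the real assignment called 0 and the highest other 0, so 4 of 4 gave as many. At an unadjusted p under 0.05 turning replicate 3 gave 735 genes against the real 705, and 1507 probes against 1398. The immediate early list had an adjusted p of 8.2e-17 as deposited and 0.0173 with replicate 3 turned, and the antigen list 2.2e-10 and 0.21.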
